A study of Arabidopsis thaliana with 24 samples.

How the data were processed

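Expression was measured on 24 Affymetrix ATH1 arrays of Arabidopsis thaliana seedling RNA, 3 for each of 8 groups: 4 genotypes (Columbia wild type, called Col here, and the mutants iaa17-6, axr3-1 and iaa5-1 iaa6-1 iaa19-1, the last called iaa5 iaa6 iaa19 or the triple mutant here), each as an ethanol control and after indole-3-acetic acid (IAA). Groups and replicate numbers were taken from the labels, which do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

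The deposited table holds 1 log2 value per probe set and array. The scale was inferred from the values, and the authors' summarization and normalization are not given in the sources used here. The lowest value is 5.64 on all arrays, the log2 of 50, and 44.4% to 46% of the values of each array lie at this floor. Array medians lay between 5.941 and 6.064. A difference against a group with all 3 arrays at the floor is a lower bound, written "at least N-fold", and no fold is given where both groups lie at the floor. A difference of responses that involves a group at the floor is a difference of floored values, not a bound. Several probe sets of a gene were not averaged.

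The 64 control probe sets were left out. A filter was set at the lowest 30% by mean value. That percentile is the floor itself, so the filter left out the 8554 probe sets at the floor on all 24 arrays, and 14192 were tested. The deposited normalization was kept. In the annotation used here, 13513 of the 22746 other probe sets name 1 gene, 503 name several and 8730 are unnamed here, not without a gene. Tests were made per probe set, and a gene in a list was represented by its brightest probe set with 1 annotated gene. Of 67 tested genes with more than 1 probe set, 0 had both past the threshold in opposite directions in the Col response. The annotation used here names no probe set for IAA17, IAA5, IAA6 or IAA19. Unnamed probe sets were tested and may include theirs, but none was assigned to these genes, so their levels give no check of the labels here.

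All 13 contrasts came from 1 limma fit of the 8 group means (limma 3.58.1 in R 4.3.3, moderated by empirical Bayes with a mean trend, 16 residual degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Adjusted p-values of single genes below are from this limma fit. The contrasts are the IAA response of each genotype, each mutant against Col within each treatment, and the difference between the response of each mutant and that of Col. Errors of log2 differences are standard errors (SE) from the fit, and levels are means ± SD over 3 arrays.

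Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and, as an alternative, an estimated one. P-values were adjusted over the lists of a contrast. Of the 17 lists fixed, those for ARF factors, auxin receptors, gibberellin and brassinosteroid metabolism and the cell cycle had 0 annotated members. Lists under 3 measured members were counted but not tested. A measured member has a probe set of its own, named here and above the floor on at least 1 array. These were 3 of 29 Aux/IAA, 4 of 11 GH3, 4 of 15 transcription factor, 7 of 20 cell wall and 3 of 26 root hair members. Most others have no probe set of their own named here, so the lists do not stand for whole families. The size of the response kept in a mutant was measured on probe sets past the threshold in the same direction in both of the other mutants, with a mean absolute log2 fold change of at least 1, so that neither compared response chose them. For iaa17-6 and the triple mutant this choice requires a response in axr3-1. For axr3-1 it requires a response in both of the mutants whose calls largely overlapped those of Col, and it leaves out probe sets that respond in axr3-1 alone. The share kept in axr3-1 therefore describes a response like that of Col, not all of its response.

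The named genes follow a rule. For each contrast these are up to 10 probe sets with the largest rise and up to 10 with the largest fall, past the threshold, at least 1 in absolute log2 fold change, with 1 annotated symbol and, for contrasts of a pair of groups, no overlap between groups. Up to 4 members past the threshold were added per list. Genes outside this rule are said to have been chosen after their values were seen. The sample groups, the tests, the lists, this rule and the alternatives, apart from those named last, were fixed before the data were examined.

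Correlations between arrays of a group were 0.958 to 0.996, and 0 pairs of arrays were identical. The number of arrays limits the precision, with a median SE of 0.152 for the difference of a pair of groups and 0.215 for a difference of responses. Same-numbered arrays were checked for shared deviations from their group means. Within iaa17-6 the correlations across probe sets of control and IAA arrays were 0.16, 0.56 and 0.7, and within iaa5 iaa6 iaa19 they were 0.84, 0.58 and 0.63. Between Col control and iaa17-6 control they were 0.33, 0.62 and 0.72. All 3 were also over 0.1 between Col control and iaa17-6 IAA (0.62, 0.42 and 0.58), Col control and axr3-1 IAA (0.3, 0.51 and 0.58), iaa17-6 control and axr3-1 IAA (0.52, 0.74 and 0.68), and iaa17-6 IAA and axr3-1 IAA (0.27, 0.58 and 0.79), group pairs that no contrast compares alone. The labels name no shared day. In each of these group pairs, the arrays of the set of 6 that stood apart, described below, carry the same number. That set alone could give such correlations, so a pairing by number cannot be told apart from it. Within Col (-0.07, 0.32 and 0.5) and axr3-1 (-0.05, -0.15 and 0.01) the numbers did not pair the arrays.

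In 5 runs on simulated data of 14192 probe sets with 200 changed, the Col response was called for 44.2% of probe sets changed 1.5-fold, 81.8% changed 2-fold and 98.2% changed 4-fold, and 5.4% of calls were false. For the difference between the axr3-1 and Col responses these were 16.7%, 54.6% and 94.5%, with 6% false. Changes were placed only in probe sets with Col control means well above the floor, and the noise of each value was drawn independently. These rates therefore do not cover probe sets that start at the floor, nor deviations shared between arrays. Alternatives were quantile normalization, median centring, other filters on low values, no mean trend, a fit of only the groups of a contrast, array weights, replicate blocks, a 2-fold rule, the mean of a gene's probe sets, other choices of responsive probe sets and each array left out in turn. After the data were seen, a block for a set of 6 arrays that stood apart, the fit without them, probe sets above the floor on all arrays, a block for Col control with iaa17-6 control, and shuffled residuals were added. The planned changes of pseudocount were not run, because the values are already on the log2 scale.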

Results

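Transcript levels were measured in 7-day-old, light-grown seedlings of Arabidopsis kept in liquid culture and given 5 µM of the auxin indole-3-acetic acid (IAA) or ethanol for 2 h at 24 °C. Wild type (Col) was set beside iaa17-6 and axr3-1, which carry different alleles of the Aux/IAA repressor gene IAA17, and beside the triple mutant iaa5 iaa6 iaa19. There were 3 arrays in each of the 8 groups, and 14192 probe sets were tested. The comparisons ask which transcripts respond to IAA, how the mutants differ from Col, and whether their responses differ.

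In Col, genes that limit or relay auxin signalling rose within 2 h. Of the 4 measured GH3 genes, whose enzymes join auxin to amino acids, 3 rose: GH3.3 by 5.86 on the log2 scale (SE 0.25, 58.1-fold, adjusted p = 5.48e-12), WES1 (also called GH3.5) 19.3-fold and GH3.1 at least 4.28-fold, from the floor. GH3.3 read 12.17 to 12.92 on the IAA arrays of the 4 genotypes, near the highest value of 13.16, where differences may be compressed, and its folds carry that limit. All 4 measured auxin-linked transcription factors rose, the lateral root regulators LBD29 at least 8.95-fold, LBD16 at least 3.99-fold and PUCHI at least 1.9-fold, and the homeobox gene HAT2 from 7.79 ± 0.22 to 10.79 ± 0.06 (SD, n = 3). Among 3 measured Aux/IAA repressors 2 rose, IAA29 at least 11.2-fold and IAA30 at least 1.6-fold. IAGLU, an auxin glucosyltransferase, rose 4.59-fold. Of 7 measured cell wall loosening genes 4 rose and 1 fell, with XTH18 up 2.38-fold and XTH19, another xyloglucan-modifying enzyme, up 2.44-fold. Falling genes included the glutathione transferases GSTU26 (log2 -1.39, SE 0.25) and GSTU28 (at least 2.06-fold lower), the transcription factor gene tny (log2 -1.28, SE 0.17) and the sugar transporter gene SFP1 (log2 -1.02, SE 0.17).

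The Col response comprised 999 probe sets, 547 higher and 452 lower, of which 230 and 89 changed at least 2-fold. Camera placed the GH3 list (adjusted p = 1.96e-08), the Aux/IAA list (adjusted p = 1.96e-08), the transcription factor list (adjusted p = 3.22e-21) and the cell wall list (adjusted p = 0.000274) above other genes. With an estimated correlation camera gave adjusted p = 0.000313, adjusted p = 0.000944, adjusted p = 1.83e-07 and adjusted p = 0.00194. Adjusted over the list alone, 3 GH3 genes, 3 Aux/IAA genes, 4 transcription factor genes and 5 cell wall genes rose, and 1 cell wall gene fell. The root hair list had 0 of 3 members past the threshold, and 2213 probe sets had an unadjusted p under 0.05. The call of IAA30 was lost without Col IAA replicate 1 (log2 at least 0.6, adjusted p = 0.0783) and without Col IAA replicate 3 (log2 at least 0.61, adjusted p = 0.0677). With only the Col arrays fitted the count was 595, and IAA30 (adjusted p = 0.0686) and XTH19 (adjusted p = 0.0521) were not past the threshold.

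**Figure D1:**
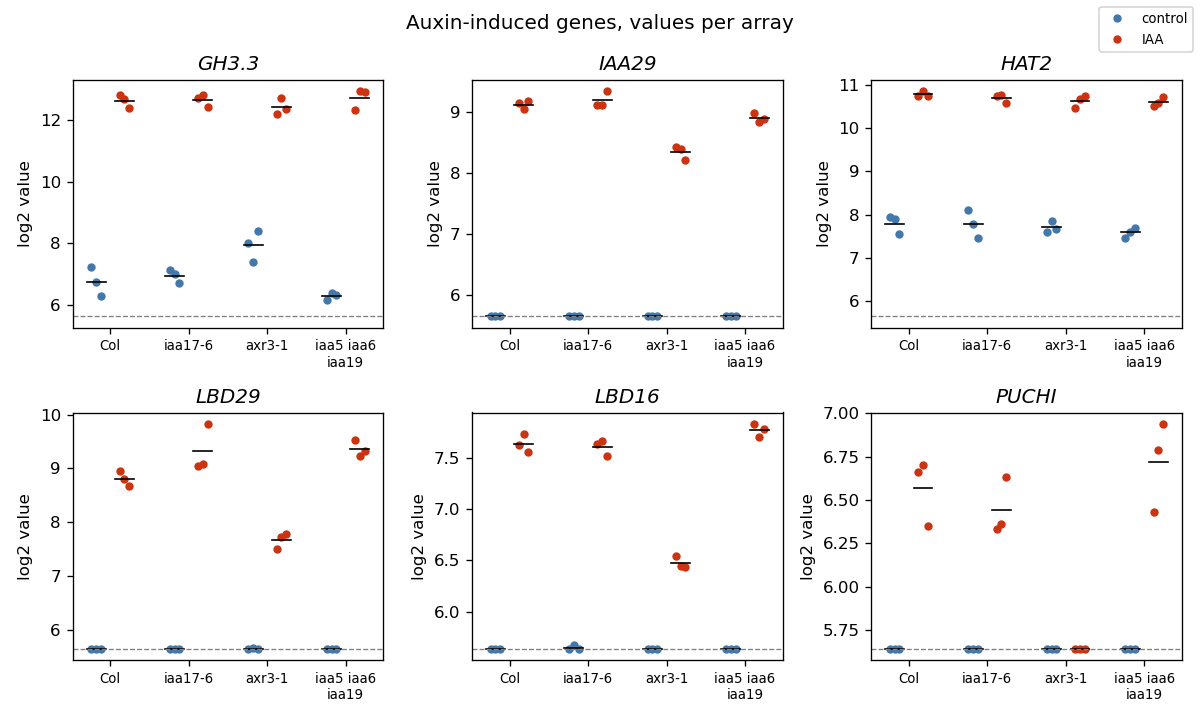
Log2 values of 6 auxin-induced genes on each array, by genotype and treatment, with points for arrays, black lines for group means and a dashed line for the floor. In axr3-1, PUCHI stayed at the floor after IAA, LBD16 averaged 6.48 against 7.64 in Col, and HAT2 averaged 10.64 against 10.79.

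In iaa17-6 and in the triple mutant, GH3.3, LBD29, IAA29 and HAT2 also rose. GH3.3, near the top of the scale after IAA, rose 51.8-fold in iaa17-6 (log2 5.7, SE 0.25) and 84.8-fold in iaa5 iaa6 iaa19 (log2 6.41, SE 0.25). LBD29 rose from the floor by at least 3.68 and at least 3.72 on the log2 scale, IAA29 at least 11.8-fold and at least 9.64-fold, and HAT2 7.56-fold and 8.1-fold. All 4 measured auxin-linked transcription factors and all 3 measured Aux/IAA genes rose in both. ARL, a gene linked to organ growth, rose 3.68-fold in iaa17-6 and 3.95-fold in the triple mutant, and tny fell by 1.53 and by 1.62 on the log2 scale (SE 0.17 in each).

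The response of iaa17-6 comprised 1096 probe sets, 626 higher and 470 lower, and shared 432 of the 547 higher Col calls (79%) and 280 of the 452 lower ones, where independent lists would share 24.1 and 15. That of iaa5 iaa6 iaa19 comprised 1032, 522 higher and 510 lower, and shared 417 (76.2%) and 323 of those of Col, against 20.1 and 16.2. These responses have no arrays in common. The root hair list lay lower in iaa17-6 (camera adjusted p = 0.0275) and in the triple mutant (adjusted p = 0.0333), with adjusted p = 0.144 and adjusted p = 0.158 with an estimated correlation. The first call was lost without iaa17-6 IAA replicate 3 (adjusted p = 0.0548), and the second without triple-mutant control replicates 2 (adjusted p = 0.109) or 3 (adjusted p = 0.0654) or IAA replicates 2 (adjusted p = 0.0756) or 3 (adjusted p = 0.102). In a fit of only its own groups the iaa17-6 count was 363. In such fits the Aux/IAA member IAA18 was not past the threshold in iaa17-6 (adjusted p = 0.0928) or in the triple mutant (adjusted p = 0.0609), and IAA30 was not in iaa17-6 (adjusted p = 0.17). IAA18 also lost its call in the triple mutant without iaa5 iaa6 iaa19 control replicate 3 (adjusted p = 0.0775) or IAA replicate 2 (adjusted p = 0.0633). Without the 6 arrays that stood apart within their groups, a set found after seeing the data, IAA18 had an adjusted p = 0.0576 in iaa17-6 and an adjusted p = 0.142 in the triple mutant.

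In axr3-1, some auxin-induced genes of Col rose and others fell short of the threshold. GH3.3 reached 12.41 ± 0.27 (SD, n = 3) after IAA, against 12.62 ± 0.22 in Col, near the top of the scale. Its control lay at 7.94 ± 0.51 against 6.76 ± 0.48, so that its rise was 22.2-fold (log2 4.47, SE 0.25), and the difference from the Col response was not past the threshold (-1.39, SE 0.35, adjusted p = 0.0525). HAT2 rose 7.63-fold (log2 2.93, SE 0.13) and 8-fold in Col, IAA29 at least 6.52-fold and LBD16 at least 1.79-fold. PUCHI and GH3.1 stood at the floor on all 3 axr3-1 arrays of either treatment. XTH19 rose 7.24-fold from 6.5 ± 0.16 to 9.36 ± 0.23 (SD, n = 3), and BGLU28, a beta-glucosidase gene, rose 2.63-fold (above the floor on 2 of 3 control arrays). WES1 had a log2 difference of 1.81 with an adjusted p = 0.0668. Of the lists, 3 of 4 transcription factors, 1 of 4 GH3 genes and 1 of 3 Aux/IAA genes rose, and 3, 3 and 1 adjusted over the list alone. Camera placed these lists above other genes in axr3-1 too (adjusted p = 1.83e-14, adjusted p = 4.38e-06 and adjusted p = 4.48e-06). It did so for the cell wall list as well (adjusted p = 0.000384), with 2 of 7 members higher. With an estimated correlation camera gave, in this order, adjusted p = 2.77e-06, adjusted p = 0.00177, adjusted p = 0.00351 and adjusted p = 0.00312. The response comprised 341 probe sets, 254 higher and 87 lower, with 106 and 4 of them at least 2-fold. It fell to 208 without axr3-1 IAA replicate 3, and to 84 with only the axr3-1 arrays fitted. Of the 547 higher Col calls 165 were also called higher in axr3-1, and of the 452 lower ones 30 were also lower, where independent lists would share 9.79 and 2.77.

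The difference between the axr3-1 and Col responses was tested directly. LBD16 (difference of log2 responses -1.16, SE 0.09, adjusted p = 4.35e-07), LBD29 (-1.14, SE 0.21), PUCHI (-0.93, SE 0.15) and IAA29 (-0.78, SE 0.12) rose less in axr3-1. The controls of these 4 genes lay at or within 0.01 of the floor in both genotypes, so these values equal differences between the IAA groups. HAT2 was the 1 transcription factor list member not past the threshold. CP1, a cysteine protease gene, rose less in axr3-1 (-1.35, SE 0.17), and BGLU28, which stood at the floor on all 6 Col arrays, rose in axr3-1 (1.39, SE 0.08). Camera placed the transcription factor list lower in axr3-1 (adjusted p = 2.68e-09), as it did the Aux/IAA list (adjusted p = 0.000785) and the GH3 list (adjusted p = 0.00196). With an estimated correlation camera gave adjusted p = 5.2e-05, adjusted p = 0.0259 and adjusted p = 0.0259. The cell wall list, with 2 members higher and 1 lower, and the root hair list were not past the threshold (camera adjusted p = 0.731 for each). Of the 4 GH3 genes 0 passed over all probe sets, and 3 passed adjusted over the list alone; 3 transcription factors and 2 Aux/IAA genes passed adjusted over the list alone. In all, 230 probe sets differed, 106 with a higher and 124 with a lower response in axr3-1, and 1283 had an unadjusted p under 0.05. Among probe sets above the floor on all 24 arrays the count was 46, and with the lowest 60% left out it was 92. The set of 6 arrays that stood apart holds Col control replicate 3 and axr3-1 IAA replicate 3. It holds no Col IAA or axr3-1 control array, so it is unbalanced in this difference. Of the 15 named calls of this contrast, 5 were lost without the 6 arrays.

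On 220 probe sets that rose in both other mutants, the median log2 response was 1.47 in Col and 0.83 in axr3-1, or 56.4% of that in Col, and it was smaller in axr3-1 for 186 of them (camera p = 1.12e-50, p = 3.15e-06 with an estimated correlation). On 104 that fell, it was -1.11 in Col and -0.16 in axr3-1, or 14.4%, and smaller for all 104 (camera p = 2.09e-77, p = 1.59e-06 with an estimated correlation). For the falling probe sets the axr3-1 control arrays were already lower than those of Col, with a median difference of -0.59. For the rising ones this difference was -0.01. By their choice, neither set could hold probe sets that responded in axr3-1 alone, so these shares describe only responses seen in the other mutants.

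**Figure D2:**
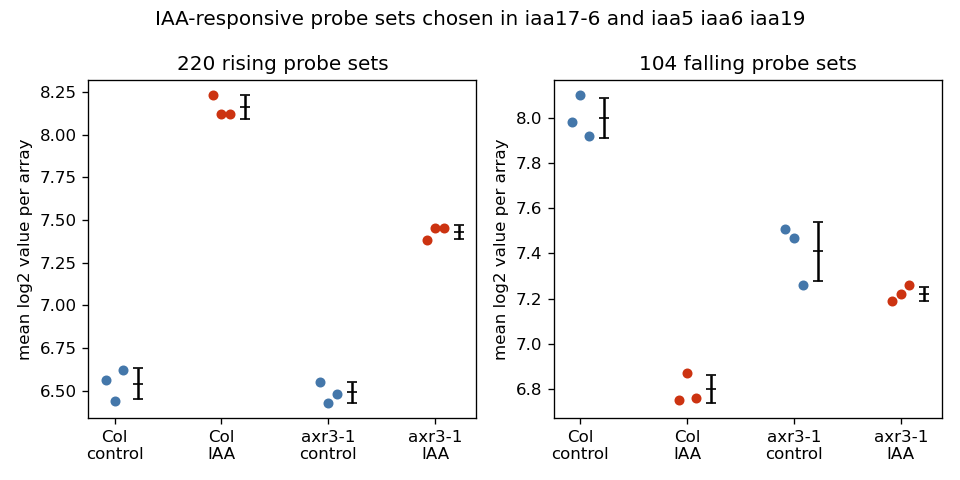
Mean log2 value per array over 220 rising and 104 falling probe sets chosen in iaa17-6 and iaa5 iaa6 iaa19, with points for arrays and bars for the mean and SD of 3 arrays. The rising set averaged 8.16 in Col and 7.43 in axr3-1 after IAA, and the falling set averaged 8 in Col and 7.41 in axr3-1 in control.

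Without IAA, axr3-1 seedlings had lower transcripts of root hair and cell wall loosening genes than Col. All 3 measured root hair genes, of 26 listed, were at the floor on every axr3-1 control array. They were the expansin genes EXPA18 (at least 3.39-fold lower, adjusted p = 5.47e-06) and EXPA7 (at least 2.07-fold lower) and the xyloglucan endotransglucosylase gene XTH26 (at least 2.64-fold lower). Of 7 measured cell wall loosening genes 4 were lower, among them EXPA8 (log2 -2.18, SE 0.35, above the floor on 1 of 3 axr3-1 arrays), XTH19 (log2 -1.25, SE 0.27) and EXPB1 (at least 1.48-fold lower). The cellulase gene GH9C1, at the floor on the 3 axr3-1 control arrays, had a log2 difference of -1.66 or beyond, a bound. Among the genes higher in axr3-1, PPDK, pyruvate orthophosphate dikinase, was 3.67-fold higher (log2 1.88, SE 0.16). ICL, isocitrate lyase of the glyoxylate cycle, was 7.08-fold higher (log2 2.82, SE 0.62). PWD, another dikinase gene, was 2.84-fold higher (above the floor on 1 of 3 Col arrays). FMO, a monooxygenase gene, was 3.83-fold higher, and GH3.3 2.26-fold (log2 1.18, SE 0.25).

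In control, 1285 probe sets differed between axr3-1 and Col, 660 higher and 625 lower. Camera placed the root hair list (adjusted p = 1.06e-06) and the cell wall list (adjusted p = 0.000132) lower in axr3-1, and 3 and 4 members were lower adjusted over the list alone. With an estimated correlation camera gave adjusted p = 0.00579 and adjusted p = 0.00366. The root marker PYK10 differed by 0.02 between these groups (95% interval -0.21 to 0.24), and the 2 measured photosynthesis genes had a median difference of 0.01. With only these 6 arrays fitted the count was 482, and EXPA8 (adjusted p = 0.0595), EXPA7 (adjusted p = 0.0757), GH3.3 (adjusted p = 0.193) and ICL (adjusted p = 0.128) were not past the threshold. Over probe sets above the floor on all arrays the cell wall list had an adjusted p = 0.0512.

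With IAA, 1095 probe sets differed between axr3-1 and Col, 599 higher and 496 lower. EXPA18 (at least 3.05-fold), EXPA7 (at least 2.46-fold) and XTH26 (at least 2.09-fold) were again lower, as were EXPA8 (log2 -2.36, SE 0.35), LBD16 (log2 -1.16, SE 0.07) and GH3.1 (at least 4.28-fold). FMO (3.56-fold), PPDK (2.6-fold) and PWD (2.55-fold, above the floor on 1 of 3 Col arrays) were higher. With only these arrays fitted the count was 656, and XTH26 was not past the threshold (adjusted p = 0.0553).

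**Figure D3:**
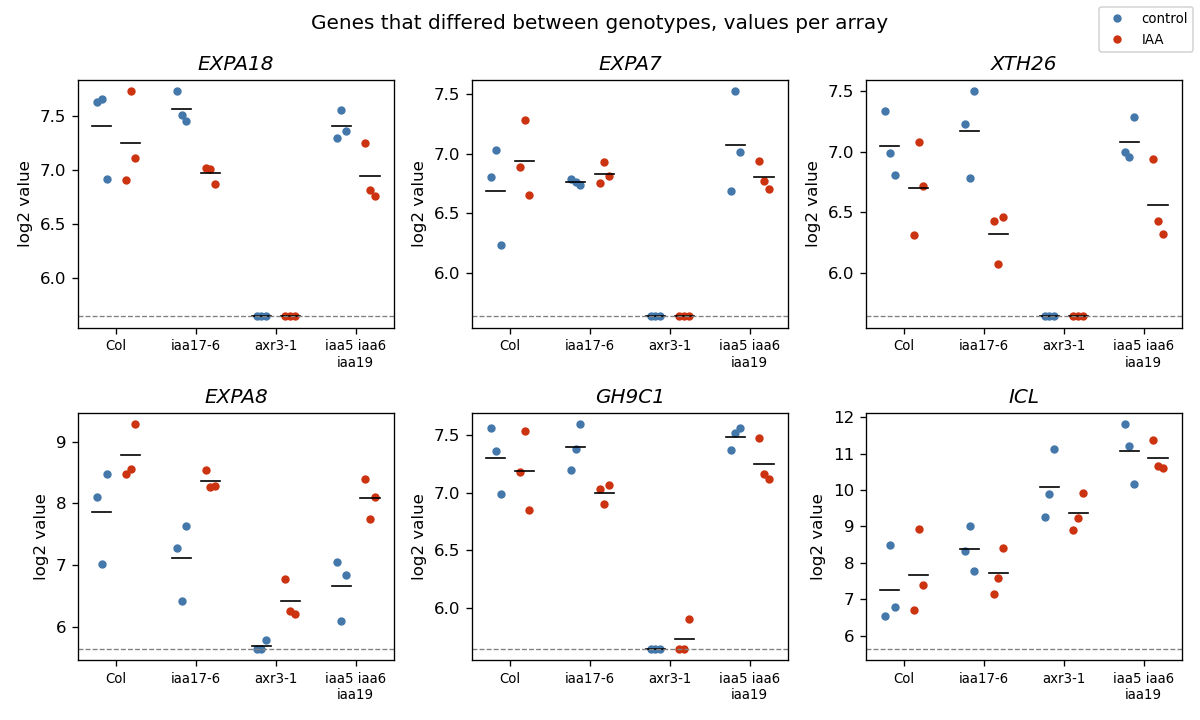
Log2 values of 6 genes that differed between genotypes, on each array, with points for arrays, black lines for group means and a dashed line for the floor. EXPA18, EXPA7 and XTH26 lay at the floor on all 6 axr3-1 arrays.

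Between iaa17-6 and Col in control, 28 probe sets differed, 17 higher and 11 lower, and 0 of them had a symbol. The locus AT2G04460, chosen after its values were seen, was higher in iaa17-6 in control (log2 2.09, SE 0.15, adjusted p = 2.94e-07) and with IAA (log2 1.8, SE 0.15). It was not the largest difference. Among the calls the largest log2 difference was 3.29 in size in control and 3.8 with IAA. These lay in probe sets for which the annotation used here names no single gene. Whether they belong to the mutated gene was not analysed. In iaa5 iaa6 iaa19, ICL was 13.9-fold higher than in Col in control (log2 3.79, SE 0.62, adjusted p = 0.0124) and 9.17-fold with IAA (log2 3.2, SE 0.62, adjusted p = 0.0401). The 3 Col control arrays spread widely for ICL (7.27 ± 1.06, SD, n = 3). In the triple mutant 25 probe sets differed in control, 12 higher and 13 lower, and 7 higher and 13 lower after quantile normalization or median centring. With IAA, 15 differed for iaa17-6 and 21 for the triple mutant.

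These counts moved with single arrays, and some moved further with array weights or with only the groups of a contrast fitted, as given below. For iaa17-6 in control the count was 10, 71 and 8 without Col control replicates 1, 2 and 3, and 17 without iaa17-6 control replicate 1 or replicate 3. For the triple mutant in control it was 2, 81 and 10 without Col control replicates 1, 2 and 3, and 16 and 8 without its own replicates 1 and 2. With IAA, the iaa17-6 count was 27 without iaa17-6 IAA replicate 1 and 85 without replicate 2. The triple mutant's was 11 without Col IAA replicate 3, and 6 and 8 without its own IAA replicates 2 and 3. With a replicate block for Col control and iaa17-6 control, whose same-numbered arrays shared deviations, the control count was 43. Without the 6 arrays that stood apart it was 11 for each of these mutants in control, and for iaa17-6 it was 101 with this array set as a block. The ICL call in control was lost without Col control replicate 1 (adjusted p = 0.121) or replicate 3 (adjusted p = 0.0905), or without triple-mutant control replicate 1 (adjusted p = 0.0577) or replicate 2 (adjusted p = 0.0642). It was also lost with only its groups fitted and without the 6 arrays, with a highest adjusted p = 0.544 over all alternatives. With IAA the ICL call was lost without each array except Col IAA replicate 2, with a highest adjusted p = 0.206. There it was also lost with only its groups fitted, without a filter and without the 6 arrays (highest adjusted p = 0.257 over all alternatives).

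The IAA responses of these mutants differed from that of Col for 4 probe sets in iaa17-6 and 5 in iaa5 iaa6 iaa19, all named here after their values were seen. In the triple mutant, 3 probe sets that are unnamed here responded less than in Col, with differences of log2 responses of -3.56 (SE 0.17, adjusted p = 3.07e-10), -2.58 (SE 0.22) and -1.88 (SE 0.15). Whether they belong to the genes mutated in this line was not analysed here, so these differences are not read as an altered response of other genes. That with the largest difference rose from the floor to 9.2 ± 0.18 (SD, n = 3) in Col and stood at the floor on all 6 arrays of the triple mutant. The others were AT5G60760 (-0.75, SE 0.13) and AT5G01015 (0.66, SE 0.07), which lay at the floor after IAA in both genotypes and differed in control. In iaa17-6 these were AT3G32030 (-1.06, SE 0.16), a probe set unnamed here (0.68, SE 0.1), AT5G01015 (0.61, SE 0.07) and AT3G14280 (-0.38, SE 0.06). All of these but the unnamed probe set lay at the floor after IAA in both genotypes and differed in control. After quantile normalization or median centring, 2 of the iaa17-6 probe sets had a higher and 1 a lower response. With a replicate block within genotype the limma count for iaa17-6 was 0, with 539 probe sets at an unadjusted p under 0.05. It was 8 and 9 without iaa17-6 IAA replicates 1 and 2, and the triple mutant's was 8 without its IAA replicate 1.

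The Aux/IAA list lay higher (camera adjusted p = 0.0294) and the root hair list lower (adjusted p = 0.0294) in the iaa17-6 response than in that of Col, with 0 members past the threshold, 305 probe sets at an unadjusted p under 0.05 and, for each list, adjusted p = 0.192 with an estimated correlation. Without Col IAA replicate 2, each had an adjusted p = 0.338, and both were also lost without Col control replicate 3, iaa17-6 control replicate 3 or iaa17-6 IAA replicates 1 or 3 (highest adjusted p = 0.549). The Aux/IAA call was further lost without Col control replicates 1 or 2 (adjusted p = 0.08 and adjusted p = 0.0728). Over all alternatives the Aux/IAA call was lost in 15 of 25 and the root hair call in 11 of 24 (highest camera adjusted p = 0.692 for each). Both were lost with the replicate block within genotype. In the triple mutant the transcription factor list responded more (adjusted p = 0.00401, adjusted p = 0.0182 with an estimated correlation) with 0 of 4 members past the threshold and 205 probe sets at an unadjusted p under 0.05. Its call was lost without Col IAA replicate 3 (adjusted p = 0.0931) or triple-mutant IAA replicate 3 (adjusted p = 0.0728). The GH3 list had a mean difference of 0.21 (adjusted p = 0.0872) and passed the threshold in 9 of 26 alternatives, with means of 0.06 to 0.5 over all of them and an adjusted p = 0.000228 without the 6 arrays that stood apart. On 121 rising probe sets the median response was 1.63 in Col and 1.84 in iaa17-6 (camera p = 8.34e-07, p = 0.0637 with an estimated correlation). On 129 it was 1.56 in Col and 1.86 in the triple mutant (camera p = 1.33e-05, p = 0.115 with an estimated correlation). For these 129 the triple mutant lay below Col in control (median difference -0.18) and with IAA (-0.12). For the 121, iaa17-6 differed from Col by -0.05 and 0.03. Both sets were required to respond in axr3-1. Probe sets chosen from the Col response instead gave differences of 0.03 and 0.02, neither past the threshold. That choice uses 1 of the compared responses and favours a larger value in Col. The iaa17-6 difference of 0.21 was 0.09 without Col control replicate 3 and 0.13 without iaa17-6 control replicate 1. The triple-mutant difference of 0.29 was 0.11, 0.17, 0.19 and 0.18 without Col control replicate 3, Col IAA replicate 2, iaa17-6 IAA replicate 2 and axr3-1 control replicate 1. The root hair list responded with a further fall in the triple mutant (camera adjusted p = 0.0368, adjusted p = 0.166 with an estimated correlation), a call lost without 6 of the 12 arrays taken 1 at a time: Col control replicate 3 (adjusted p = 0.345), Col IAA replicate 2 (adjusted p = 0.408), triple-mutant control replicates 2 and 3 (adjusted p = 0.0733 and adjusted p = 0.114) and IAA replicates 2 and 3 (adjusted p = 0.167 and adjusted p = 0.147).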

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

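The tests of the axr3-1 response without the 6 arrays and after quantile normalization, the PYK10 test, the counts over other splits of the arrays and the use of shuffled residuals were chosen after the results they concern had been seen. All results here stand out because a mutant's IAA response was tested against that of Col and differed.

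The number of probe sets whose response differed was 4 for iaa17-6, 230 for axr3-1 and 5 for iaa5 iaa6 iaa19. As given above, most of the iaa17-6 calls and the named loci of the triple mutant lay at the floor after IAA in both genotypes. These differed in control. The other calls of the triple mutant are unnamed here, and whether they belong to its mutated genes was not analysed. In axr3-1 the difference of log2 responses was -1.35 for CP1, -1.22 for scpl28, -1.16 for LBD16, -1.14 for LBD29, -0.93 for PUCHI, -0.78 for IAA29, -0.64 for XTH33 and -1.08 for EXPA20. It was 1.57 for XTH19, 1.46 for GSTU26, 1.39 for BGLU28, 1.28 for XTH16, 1.25 for tny, 1.07 for STOMAGEN and 0.57 for EXPB1. The calls of XTH19, GSTU26, XTH16, STOMAGEN and EXPA20 were lost without each of the 12 arrays in turn, up to an adjusted p of 0.124, 0.116, 0.123, 0.131 and 0.133, apart from these. XTH19 passed without Col control replicate 1 or Col IAA replicate 3, GSTU26 without replicate 1 of axr3-1 control or of axr3-1 IAA, XTH16 without Col control replicates 1 or 2 or Col IAA replicate 3, STOMAGEN without Col control replicate 2, and EXPA20 without axr3-1 IAA replicate 1. EXPB1 lay at the floor in all these groups but Col control, and scpl28 lay at the floor in axr3-1. In a fit of only the Col and axr3-1 arrays, tny had an adjusted p = 0.0628 and scpl28 an adjusted p = 0.0807.

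Among lists, the mean difference of log2 responses over the members was 0.31 for Aux/IAA repressors and -0.38 for root hair genes in iaa17-6, and 0.21 for auxin-linked transcription factors and -0.34 for root hair genes in iaa5 iaa6 iaa19. With an estimated correlation the iaa17-6 calls were lost (adjusted p = 0.192 for each list), as was that of the root hair genes in the triple mutant (adjusted p = 0.166), while the transcription factors kept theirs (adjusted p = 0.0182). In axr3-1 it was -0.52 for Aux/IAA repressors, -1.37 for GH3 genes and -0.82 for auxin-linked transcription factors. For responsive probe sets, the difference of median log2 responses was 0.21 for those rising in iaa17-6, 0.29 for those rising in iaa5 iaa6 iaa19, -0.64 for those rising in axr3-1 and 0.95 for those falling in axr3-1. The calls of the first 2 were lost with an estimated correlation (p = 0.0637 and p = 0.115).

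The smaller IAA response of axr3-1 was weighed against 3 technical explanations and chance: the 6 arrays that stood apart were excluded as its whole cause, with a difference of -0.66 for the rising probe sets without them, as was the floor, with -0.57 over the 117 rising probe sets above it on all 12 arrays. A difference between arrays in the distribution of the deposited values was excluded as its whole cause. After quantile normalization the values were -0.61 for rising and 0.97 for falling probe sets. This step cannot undo the authors' own normalization, which stays open. For the falling probe sets only the real split was as large (1 of 100). The median over probe sets of their own response differences was 0.92 in size, against a highest other of 0.77. These splits exchange genotypes within a treatment, so they test any genotype difference and not the response alone. They also ignore deviations shared by same-numbered arrays, so chance is not called excluded by them. With residuals of the additive model shuffled, 2 of 100 gave a count of at least 230, the real one included, a share under 0.05. The highest other was 241, and shuffling ignores the deviations that same-numbered Col control and axr3-1 IAA arrays shared. Chance is therefore not called excluded for this count, which was 244 with a replicate block over all groups. The splits as large for the rising probe sets (10 of 100, by the same median 0.68 against 0.82) and for the count (9 of 100, 230 against 566) do not decide, since each but the real one kept the genotypes whole in 1 treatment and mixed them in the other, which turns a genotype difference into a response difference. Means of the rising set after IAA were 7.38 to 7.45 on the axr3-1 arrays and 8.12 to 8.23 on those of Col, a gap beyond their spread. For the chosen probe sets, the smaller response thus stands as a result of contrasts fixed before the data were examined. Only a biological cause for it remains a hypothesis, since the explanations were weighed on the same data.

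The lower root hair and cell wall genes of axr3-1 in control were weighed against the 6 arrays and against less root tissue. For the root hair genes the 6 arrays were excluded as the whole cause, as their median was -1.52 without them, against axr3-1 values at the floor. This test was not made for the cell wall list. Its mean lay between -0.92 and -0.6 over all alternatives, the fit without the 6 arrays among them. Less root tissue remains open: the PYK10 difference was 0.02 (95% interval -0.21 to 0.24), but this is a single marker, with a mean of 12.37 in Col near the highest value of 13.16, where a difference could be compressed. A difference in root hair growth between the genotypes was not tested.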

How the results depend on the processing

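The array set block, the fit without 6 arrays, the probe sets above the floor on all 24 arrays and the block of Col control with iaa17-6 control were chosen after the data were seen. No result changed sign where either value was past its threshold. Values with no call did, such as the difference of medians of 2 falling probe sets in iaa17-6 (0.07) and the mean of the cell wall list for the axr3-1 response minus that of Col (-0.06, range -0.14 to 0.03). Of 159 calls of named genes, 33 were lost with an array left out, 55 with only the groups of the contrast fitted, 17 without a filter and 16 without the 6 arrays. Of 50 list results, calls were lost for 5 with an estimated correlation, 4 with the array set block, 4 with only the groups of the contrast fitted, 3 with array weights, 3 with a replicate block within genotype, 3 without the 6 arrays, and 1 each without a filter, with the lowest 60% left out and over probe sets above the floor. All of these but the last, the cell wall list of axr3-1 in control, were the Aux/IAA list in the iaa17-6 response minus that of Col, or the root hair list in the responses of iaa17-6 and the triple mutant or in their differences from Col. Calls were gained by the GH3 list of the triple-mutant response minus that of Col (9 of 26 alternatives), its cell wall list (2 of 26) and its Aux/IAA list (1 of 25). Counts are given in the order Col, iaa17-6, axr3-1 and triple-mutant responses, then the mutants against Col. Unless a value's construction shows it (fewer probe sets tested, fewer arrays, a fold rule), the cause of a change was not tested. Values at the floor limit what can be seen of low transcripts.

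With the lowest 60% left out, the IAA responses comprised 611, 638, 190 and 611 probe sets. In control 8 differed for iaa17-6, and with IAA 1 for iaa17-6, 651 for axr3-1 and 7 for the triple mutant. The responses differed for 0 (limma, 108 at an unadjusted p under 0.05), 92 and 2. Without a filter, 13 differed for the triple mutant in control. Over probe sets above the floor on all arrays, the responses comprised 576, 562, 144 and 561, the mutants differed by 6, 852 and 15 in control and by 0 (limma, 933 at an unadjusted p under 0.05), 583 and 1 with IAA, and the responses differed for 0 (132), 46 and 1. With the 2-fold rule these were 319, 352, 110 and 350, then 9, 346 and 11, then 5, 316 and 6, and last 1, 120 and 3.

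With only the groups of a contrast fitted, the responses of Col, iaa17-6 and axr3-1 comprised 595, 363 and 84. In control 2, 482 and 0 (limma, 879 at an unadjusted p under 0.05) differed for iaa17-6, axr3-1 and the triple mutant, with IAA 2, 656 and 11, and the responses of iaa17-6 and the triple mutant differed for 1 and 10. With array weights, whose fit stopped before its tolerance was reached, the Col and triple-mutant responses comprised 1753 and 2348. In control 141 and 221 differed for iaa17-6 and the triple mutant, with IAA 1698 for the triple mutant, and its response differed for 20.

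With a replicate block over all groups, 53 and 32 differed for the triple mutant in control and with IAA. With a replicate block within genotype, the axr3-1 response comprised 672, and the responses differed for 0 in iaa17-6 (limma, 539 at an unadjusted p under 0.05) and 363 in axr3-1, whose arrays share only a number. With the block of Col control and iaa17-6 control, 43 differed for iaa17-6. No other count moved by over 1.5 times with a replicate block. With the array set as a block 101 differed for iaa17-6 in control, and without the 6 arrays 11 for iaa17-6 and 11 for the triple mutant. With probe sets chosen from the Col response, the differences of medians were 0.03 (rising, iaa17-6, no longer past the threshold), 0.06 (falling, iaa17-6, now past it) and 0.02 (rising, triple mutant, no longer past it).

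Leaving out each array in turn gave 757 to 855, 855 to 1004, 208 to 331 and 759 to 945 for the responses. Against Col in control the ranges were 8 to 71 (iaa17-6), 933 to 1292 (axr3-1) and 2 to 81 (triple mutant), and with IAA 11 to 85, 755 to 977 and 6 to 25. Differences of responses gave 3 to 9, 161 to 208 and 4 to 8. Differences of medians ranged from -0.67 to -0.56 and from 0.85 to 1 in axr3-1 (rising, falling), from 0.09 to 0.29 and from -0.13 to 0.17 in iaa17-6, and from 0.11 to 0.31 and from 0 to 0.19 in the triple mutant, where the falling sets of the last pair of mutants hold 2 probe sets each.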

Other observations

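The counts over other splits of the arrays, the shuffled residuals and the families of genes were chosen after the results were seen. Among 33 families named by symbol, tested over 10 contrasts (330 tests), 15 tests passed with the preset correlation and 1 with an estimated one. The latter was that of symbols starting with GH, a mixed group of GH3 enzymes and GH9 cellulases, which rose in the triple mutant for 4 of 9 members, GH3.3, GH3.1, GH9B13 and GH9C2 (camera adjusted p = 3.7e-05, adjusted p = 0.0154 with an estimated correlation). In Col the same 4 members rose (adjusted p = 0.00305, adjusted p = 0.0805 with an estimated correlation). Of the others, XTH genes were lower in axr3-1 than in Col in control for 4 of 7 members (camera adjusted p = 0.00305, adjusted p = 0.461 with an estimated correlation) and EXPA genes for 4 of 7, with 1 higher (adjusted p = 0.0172, adjusted p = 0.376 with an estimated correlation). SWEET genes, which encode sugar transporters, fell after IAA in Col for 2 of 5 members (adjusted p = 0.00566, adjusted p = 0.461 with an estimated correlation), and TBL genes for 3 of 14 (adjusted p = 0.0442, adjusted p = 0.461 with an estimated correlation).

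Lists with under 3 measured members were counted. In Col after IAA, the only measured SAUR gene, of 35 listed, rose from the floor by at least 0.59 (log2) and the auxin transport gene WAG2 by at least 0.85. The call of WAG2 was lost without Col IAA replicate 1 (adjusted p = 0.0512) or replicate 2 (adjusted p = 0.0974). The median log2 differences were -0.02 for 2 auxin synthesis and conjugation genes, 0.14 for 1 ethylene gene, 0.02 for 1 cytokinin gene, 0.74 for 2 touch and stress genes, 0 for 2 photosynthesis genes and 0.07 for 1 root marker, with 0 of these past the threshold by limma and 2213 probe sets at an unadjusted p under 0.05.

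A set of 6 arrays stood apart within their groups: replicate 3 of Col control, iaa17-6 control, iaa17-6 IAA and axr3-1 IAA, and replicate 1 of both triple-mutant groups. The first component of the deviations held 47.1% of their variance, and the set difference passed the threshold for 5999 probe sets, 3361 higher and 2638 lower. The set was chosen by that component from the same values. A large count was therefore favoured by the choice and is no test of the set. After quantile normalization this share was 47.5%, so a remaining difference in the distribution of the deposited values was excluded as the cause. The arrays were already alike in their distributions, and this step cannot undo the authors' own normalization, which stays open. A measurement difference of single probe sets may remain, since r was 0.32 across 67 genes with a pair of probe sets (95% interval 0.06 to 0.56), which are not independent replicates. Degraded RNA may also remain, since the 3' minus 5' difference of the controls was higher on the 6 arrays by 0.14 (SE 0.03, 95% interval 0.07 to 0.2, in 6 of 6 groups), a value that met both bounds of its prediction because they overlapped.

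For the 10 contrasts of a pair of groups, 10 splits of 6 arrays are too few for a share under 0.05, and 1 split, the real one, gave a count as large in each. The real count and the highest other were 999 and 9 for the Col response, 1096 and 28 for iaa17-6, 341 and 6 for axr3-1 and 1032 and 1 for the triple mutant. Against Col in control they were 28 and 9, 1285 and 3, and 25 and 14 for iaa17-6, axr3-1 and the triple mutant, and with IAA 15 and 3, 1095 and 0, and 21 and 3. For differences of responses, 6 of 100 splits gave a count as large for iaa17-6 (4 against 181) and 6 of 100 for the triple mutant (5 against 356). The split with 181 exchanged the genotypes in 1 treatment, which turns a genotype difference into a response difference, but splits that mixed them in both treatments gave 4 and 5 for iaa17-6, and chance stays open there. The triple-mutant split with 356 also mixed them in both treatments, and other splits that placed the set of 6 arrays alike gave 4 or fewer, so what set it apart is open. With shuffled residuals, 3 of 100 gave at least 4 calls for iaa17-6 (highest other 115), but shuffling ignores the deviations that its same-numbered arrays shared. With a replicate block within genotype its limma count was 0, with 539 probe sets at an unadjusted p under 0.05. For the triple mutant 1 of 100 gave at least 5 (highest other 2), the count was 4 with that block and 5 with a replicate block over all groups, and the largest difference was -3.56 (SE 0.17), which excludes chance for that probe set. Splits of responsive probe sets were compared by the size of the median of their response differences, not by the difference of medians. Chance was not excluded for the rising probe sets of iaa17-6 (16 of 100 splits, 0.18 against 0.37) or of the triple mutant (39 of 100, 0.14 against 0.37), nor for the falling ones, only 2 probe sets in each (69 of 100, 0.07 against 0.37, and 57 of 100, 0.07 against 0.29).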
